A study of Mus musculus with 547 samples.

How the data were processed

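RNA from mouse fetal liver cells was measured in 18 bulk libraries and 529 single cells. The bulk libraries held DLK+ sorted cells, with 2 libraries at each of 9 stages from E10.5 to E18.5. The single cells were sorted through a DLK+ or an EpCAM+ gate, picked one by one with a mouth pipette and amplified by Smart-seq2, per the labels' protocols. Of these cells, 447 came straight from embryos and 82 from liver lobes of E12.5 embryos that were cultured for 2 days as explants. The cell type used here is the putative type that the authors gave each cell in the labels, hepatoblast/hepatocyte or cholangiocyte.

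TopHat2 2.1.0, Bowtie2 and HTSeq 0.6.0 on the GRCm38/mm10 build are named in the submitters' processing notes. The bulk libraries were made from poly(A) RNA with a directional kit, per the labels' protocols, but the strand setting of the counting is not stated, so reads of overlapping genes on opposite strands cannot be told apart. The deposited files give raw read counts per gene, a count for each of 40824 genes and 92 ERCC spike-in RNAs, with no normalization by the authors. A further deposited table holds a score per gene and stage for the bulk libraries, which the authors made by pooling both libraries of a stage. From its values, this score is the summed count divided by gene length, scaled to TPM and multiplied by 1 factor per stage, of unstated origin, that ran from 0.542 to 1.84. The score was compared with the counts and not tested, and all results here start from the counts. Values of TPM per cell were recomputed from the counts and the deposited gene length, another value given per gene by the authors. A total of 145 genes share a symbol with another gene and are told apart by their Ensembl identifiers. Gene positions and types are from GENCODE M21 on GRCm38.

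Totals ran from 14385574 to 22791119 reads per bulk library and from 763480 to 2111839 reads per cell, with a median of 1098050. Each cell had reads for 6682 to 11267 genes, with a median of 9038. ERCC reads took 0.482 to 8.56% of a cell's reads, with a median of 1.99%, and were left out of library sizes and tests. The protocol has no molecular identifiers, so intervals and floors given here cover counting error only.

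Cells are not replicates of each other. Reads were therefore summed over the cells of a group that share the set number in their titles, with at least 2 cells per sum, and the sums served as replicates. Of 46 sums from embryos and 13 from explants, 42 and 10 were tested, with 1935026 to 28130886 reads each. The labels do not say whether a set is a litter, a sort or a plate, so every p-value measures only the spread between sets, part of which may be technical.

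Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test (glmQLFit and glmQLFTest) after TMM normalization and filterByExpr at its default minimum count of 10. Benjamini-Hochberg adjusted p-values below 0.05 within a comparison were called. All bulk libraries were fitted together with stage as the term, and all sums from embryos together with the group of stage, gate and annotated type as the term. The EpCAM+ explant sums were fitted with treatment and deposit round as terms, since sets 1 and 2 and sets 3 and 4 are described differently in the labels and controls are in both. Levels are normalised CPM, mean ± SD over replicates, and changes are log2 fold changes ± SE from the fit, with SE taken as the change divided by the square root of F. Where every library of a side had 0 reads, the change is given as a lower bound, with 3 reads per library as the most that a count of 0 allows. Where a side had only 1 to 3 reads, only levels are given.

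The 26 gene lists (352 genes, of which Ahsp was not found) and the rule for naming genes were fixed before the data were examined. So were all comparisons, tests and alternatives except those named below as added. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Counts of changed list members are over all genes tested, and where they differ those adjusted over the list alone are also given. Genes are named by rule. Of the called genes with a mean of at least 10 CPM in the higher group and no overlap between the replicate values of both groups, the 10 largest rises and 10 largest falls are taken, leaving out predicted, mitochondrial, haemoglobin and spike-in genes, and with fewer than 5 such genes the 5 with the smallest p. To these come up to 4 called members of each list, or up to 2 with the highest mean where none was called, and the markers Dlk1, Epcam, Afp, Alb, Sox9, Krt19 and Spp1. The text gives a selection of these. Genes outside the rule are said to be so. Results for some withheld genes are not reported here.

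A score per cell was the mean of log2(TPM + 1) over a list. The share of cells annotated as cholangiocytes has an exact binomial interval (Clopper-Pearson, 95%), and its correlation with embryonic day over sets has a two-sided permutation p from 100000 resamples (scipy 1.17.1). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.

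The fits were tested on simulated counts drawn for the real genes, with about 200 genes changed 2-fold or 4-fold. For bulk E18.5 against E10.5, 26.8% of 2-fold and 73.2% of 4-fold changes were recovered, and for picked cells E17.5 against E10.5, 17.2% and 38.4%. For annotated cholangiocytes against hepatoblasts and hepatocytes, the shares were 35.4% and 50.5%. They were 7% and 32.3% within the EpCAM+ gate, 9.1% and 25.3% for cholangiocytes E17.5 against E14.5, and 28.3% and 54% between gates. In all 5 explant comparisons, 0% of 2-fold and 0% of 4-fold changes were recovered, so changes of this size can be missed there. Between 1.2% and 5.8% of calls were false in the simulations outside explants, and no changed gene was called with the wrong sign. In explants the only call, for both drugs against U0126, was false.

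Alternatives were DESeq2 1.42.0 size factors in the edgeR fit, DESeq2's own test, no filter on low counts, another pseudocount, equal weight for each cell, sums of at least 5 cells, leaving out the round term or the second deposit round, a replicate number as a block and each replicate left out in turn. Added after seeing the data was a correction of each bulk library's trend with GC content. Fits without the E12.5 replicate 2 and both E13.5 libraries were added too. So were the test of the difference between TPPB effects with and without U0126, and its other settings. The share correlation without the 2 sets farthest from the median day was also added then.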

Results

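Gene expression was measured in cells of the mouse fetal liver while hepatoblasts, the shared progenitors, become hepatocytes or cholangiocytes, the cells that line bile ducts. Bulk RNA was sequenced from cells sorted for DLK1, a surface protein of hepatoblasts, at 9 daily stages from E10.5 to E18.5 with 2 libraries each. These libraries held 14385574 to 22791119 reads each. Single cells from embryos of E10.5 to E17.5 were sorted for DLK1 (DLK+ gate) or for the epithelial surface protein EpCAM (EpCAM+ gate), and 447 were sequenced. A further 82 cells came from E12.5 liver lobes cultured for 2 days with solvent alone (control), with TPPB at 0.5 µM, an agonist of protein kinase C, with U0126 at 10 µM, an inhibitor of the kinases MEK1 and MEK2 of the MAPK pathway, or with both. Cells held 763480 to 2111839 reads. Reads were summed over the cells of a group and set, and these sums are the replicates. From the series description, the bulk libraries serve to time the change from hepatoblast to hepatocyte, the single cells to chart both lineages, and the explants to ask whether the MAPK pathway promotes maturation of cholangiocytes.

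The first comparison, E18.5 against E10.5 in bulk, spans the whole course of the DLK+ cells. Hepatocyte genes rose to very high levels, some from near nothing. Albumin (Alb, ENSMUSG00000029368, GRCm38 chromosome 5, 90460897 to 90476602), the main plasma protein, rose from 1502 ± 357 to 255642 ± 28548 CPM, a log2 change of 7.41 ± 0.50 (SE, adjusted p = 9.0e-09 by edgeR's quasi-likelihood test with the Benjamini-Hochberg method, n = 2 libraries per stage). The fetal plasma protein Afp (ENSMUSG00000054932, chromosome 5, 90490737 to 90508907) rose by only 2.40 ± 0.34, from 14618 ± 2177 to 76921 ± 5852 CPM. The secreted glycoprotein gene Ahsg (ENSMUSG00000022868, chromosome 16, 22891277 to 22899449) rose by 12.23 ± 0.55, from 12.8 ± 2.55 to 61377 ± 7736 CPM. Fbp1, an enzyme of gluconeogenesis (ENSMUSG00000069805, chromosome 13, 62864753 to 62888282), rose by 13.26 ± 0.65, from 0.191 to 1983 ± 258 CPM.

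Whole groups of liver functions moved together. All 12 genes of the plasma carrier and apolipoprotein list rose, with a median log2 change of 6.17. Among them were Apoh (11.53 ± 0.54), Gc (9.33 ± 0.45) and the intracellular lipid carrier Fabp1 (7.67 ± 0.29). All 19 genes of the complement and coagulation list rose, with a median of 5.85, including kininogen (Kng1, 8.47 ± 0.35). The list also holds other plasma proteins, such as haptoglobin (Hp, 12.33 ± 0.86). All 14 genes of amino acid and urea cycle metabolism rose, with a median of 5.598. Cps1, the first enzyme of the urea cycle, went from 6.47 to 6840 ± 1725 CPM, and Tat, which degrades tyrosine, rose by 7.88 ± 0.40. All 11 gluconeogenesis and glycogen genes rose, with a median of 6.96, among them Pck1 (8.35 ± 0.62), and G6pc, which releases glucose, reached 603 ± 137 CPM from 0.0469. All 12 genes of bile acid synthesis and transport rose, with a median of 9.18, including the transporter Slc10a1 (853 ± 143 against 0.114 CPM). Of 13 drug metabolism genes 12 rose, with a median of 7.68, or 6.70 with genes unseen on one side set at their bound. Among them, Cyp2f2 was at least 1066-fold higher at E18.5 (105 ± 2.69 against 0 CPM). Camera called each of these 6 lists with its preset correlation, and each had adjusted p = 0.054 with an estimated correlation.

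Lipid metabolism rose as well. All 12 genes of fatty acid oxidation and ketogenesis rose, with a median of 3.67, among them Cpt1a, which admits fatty acids to mitochondria (5.03 ± 0.23). All 12 genes of the cholesterol synthesis list rose by a median of 2.00. Among them were the enzyme Lss (2.81 ± 0.25) and Insig1 (4.78 ± 0.30), a regulator of the pathway. These lists had adjusted p = 0.066 and adjusted p = 0.45 with an estimated correlation. Of 19 liver transcription factors 12 rose and 4 fell, with a median of 1.03, and camera did not call the list (adjusted p = 0.095 with the preset correlation). Among those that rose were Cebpa (3.23 ± 0.25), Ppara (4.88 ± 0.40) and Nr1i3 (9.22 ± 0.53).

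Cell cycle genes fell, as did part of the fetal liver list. All 20 cell cycle genes fell, with a median of -3.33 and adjusted p = 0.054 with an estimated correlation. Top2a, needed to separate chromosomes, went from 476 ± 29.3 to 25 ± 10.4 CPM, and the mitotic cyclin Ccnb1 changed by -4.58 ± 0.32. Of 14 fetal liver genes 8 fell and 4 rose, and the median was -2.06, with adjusted p = 0.22 with an estimated correlation and no call without the filter on low counts. The growth factor Mdk changed by -9.07 ± 0.56 (383 ± 1.51 to 0.744 CPM) and the chromatin protein Hmga2 by -7.32 ± 0.34. Dlk1 itself (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336), on which the cells were sorted, changed by -2.48 ± 0.21, from 2403 ± 46.4 to 431 ± 11.52 CPM. Epcam (ENSMUSG00000045394, chromosome 17, 87635979 to 87651129) fell by 2.47 from 43.7 ± 6.56 CPM. Lgr5, a Wnt target (-4.13 ± 0.30), Ccnd1, a cyclin of the G1 phase (-3.94 ± 0.29), and the receptors Notch3 (-7.73 ± 0.96) and Notch1 (54.6 to 13.7 CPM) fell. Sox9, a biliary transcription factor (ENSMUSG00000000567, chromosome 11, 112782224 to 112787760), did not pass the test (-0.29 ± 0.35, adjusted p = 0.49). Spp1, a secreted protein of bile duct cells (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), rose from 0.807 to 55 ± 41.7 CPM.

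In all, 4987 genes rose and 4964 fell of 15275 tested, and 12182 differed over all stages. Markers of other cells moved in the same libraries. Of 13 stellate and mesenchymal genes 11 fell, with a median of -3.94 and adjusted p = 0.53 with an estimated correlation, among them Postn (-6.25 ± 1.19) and Pdgfrb (-5.86 ± 0.85). The mean of this list was 4.97 and 5.22 log2 CPM in the E10.5 libraries, and 1.24 and 2.62 at E18.5. The mesothelial gene Msln was called as a rise of 3.27, but the fitted change was -4.73 without E18.5 replicate 2. The endothelial gene Stab2 rose from 0.365 to 63.2 CPM, and the red cell gene Hbb-bs from 0.261 to 47.8 ± 35 CPM.

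**Figure D1:**
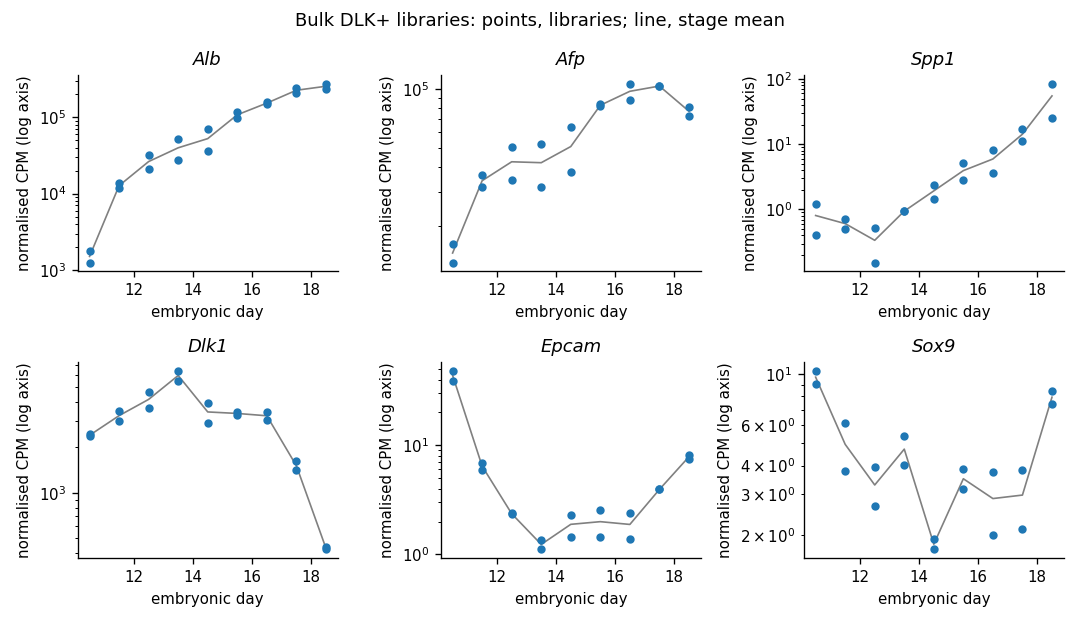
Normalised CPM on a log axis of 6 marker genes in the bulk libraries of DLK+ cells by embryonic day. Points are the 2 libraries of a stage and lines join stage means. Alb climbs from 1502 CPM at E10.5 to 255642 CPM at E18.5, while Dlk1 ends at 431 CPM.

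Contrasts of each stage with the stage before were used to time these changes. The spread between the 2 libraries of a stage was uneven. As chi-square per degree of freedom it was 10.4 at E10.5 and 9.66 at E11.5. It was 64.8 to 76.9 from E12.5 to E14.5, and 26.1 to 55.3 later. All stages were fitted together, so counts of called genes on different days do not measure only the size of the change. Between E10.5 and E11.5, 1458 genes rose and 584 fell. Alb rose by 3.08 ± 0.41 to 12732 ± 1478 CPM, Ahsg by 4.60 ± 0.40, Apoh by 3.71 ± 0.40, and the metal-binding gene Mt2 by 5.02 ± 0.41. Of the plasma carrier list 11 of 12 genes rose, or 12 adjusted over the list alone, and of the complement list 14 of 19, or 18. Both had adjusted p = 0.071 with an estimated correlation. Epcam changed by -2.76 ± 0.28, from 43.7 ± 6.56 to 6.43 CPM. The early biliary list fell, with 7 of 13 genes, or 9 adjusted over the list alone, and the junction list fell, with 8 genes down and 1 up of 17, or 13 called adjusted over the list alone. These also had adjusted p = 0.071 with an estimated correlation. Over the same day 10 of 14 genes of other blood cells rose, or 12 adjusted over the list alone, with adjusted p = 0.071 with an estimated correlation. The granulocyte enzyme Mpo went from 3.03 to 103 ± 44.5 CPM. Left-out libraries moved the count of called genes down to 651, without E10.5 replicate 2.

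From E11.5 to E12.5, the main fit called 65 genes up and 7 down of 2383 at an unadjusted p below 0.05. Several times as many were called with DESeq2 or with no filter on low counts. The glutathione transferase Gsta3 rose by 3.19 ± 0.37, Apoh by 2.27 ± 0.36 and Pck1 by 2.87 ± 0.58, while Epcam changed by -1.44 ± 0.29. The mean of the dissociation stress list was 4.02 and 3.44 log2 CPM at E11.5, 6.87 and 6.21 at E12.5, and 6.19 and 3.46 at E13.5. Camera called this list as a rise at E12.5, with 1 of 14 genes past the test and 14 adjusted over the list alone, and adjusted p = 0.39 with an estimated correlation. Without E11.5 replicate 2 the count fell to 4, and without E12.5 replicate 1 it was 423. Gsta3, Apoh, Pck1 and Epcam all lost their calls without E11.5 replicate 2, and the last 3 also without E11.5 replicate 1 or E12.5 replicate 2.

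From E12.5 to E13.5, 774 genes rose and 1440 fell, and from E13.5 to E14.5, 2351 rose and 1749 fell. Ahsg rose by 1.29 ± 0.35 and the alcohol dehydrogenase Adh1 by 1.70 on the first of these days. On the second, the cytochrome P450 gene Cyp3a11 rose by 4.81 ± 0.65 and the copper carrier Cp by 2.86 ± 0.43, while Mdk changed by -1.82 ± 0.36, Sox9 by -1.37 ± 0.38 and Dlk1 by -0.80 ± 0.20, from 5973 to 3429 CPM. Both counts moved with GC content: with each library's trend with GC content removed, 215 and 543 genes were called, and Ahsg, Adh1, Mdk and Dlk1 were no longer among them. Sox9 lost its call without E13.5 replicate 2 or either E14.5 library. Counts were also 527 without E12.5 replicate 1, 2450 without E12.5 replicate 2, and 2034 without E14.5 replicate 2.

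From E14.5 to E15.5, 29 genes rose and 4 fell (1929 at an unadjusted p below 0.05). Those that rose include Fbp1 (4.03 ± 0.45, to 37.2 ± 16.6 CPM), Slc10a1 (2.87 ± 0.44) and the urate oxidase gene Uox (2.42 ± 0.37). The gluconeogenesis and bile acid lists rose with 2 and 1 genes past the test, 9 and 9 adjusted over the list alone, and both had adjusted p = 0.088 with an estimated correlation. The count was 0 without E14.5 replicate 1 and 612 without E14.5 replicate 2. From E15.5 to E16.5 edgeR called 0 genes, with 851 at an unadjusted p below 0.05, 7 called by DESeq2 and 323 by edgeR with no filter. In simulated data for this contrast 41.4% of 2-fold and 68.7% of 4-fold changes were recovered. Without E16.5 replicate 2, 14 genes were called.

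Late gestation brought further changes. From E16.5 to E17.5, 900 genes rose and 1101 fell, with 728 in all without E16.5 replicate 2 and 799 without E17.5 replicate 1. The prolactin receptor Prlr rose by 8.64 ± 0.50 (0.138 to 60.2 CPM), Cyp2c40 by 5.72 ± 0.33 and the fatty acid hydroxylase Cyp4a10 by 6.29. Fbp1 rose by 3.74 ± 0.41, G6pc by 4.39 ± 0.58, Cyp2e1 by 4.27 ± 0.43, and Ugt1a1, which conjugates bilirubin, by 5.38 ± 0.44. Of 20 cell cycle genes 19 fell, with a median of -1.33 and adjusted p = 0.16 with an estimated correlation. Of 14 fetal liver genes 6 fell, or 7 adjusted over the list alone, with adjusted p = 0.26 with an estimated correlation. Dlk1 fell from 3234 ± 253 to 1512 ± 143 CPM and the fetal liver regulator Cited1 by -2.84 ± 0.17. The macrophage genes Cd5l (-4.05 ± 0.82, not called without E16.5 replicate 2) and Marco (-3.62) fell over the same day. From E17.5 to E18.5, 470 genes rose and 678 fell, with 581 and 515 in all without E17.5 replicate 1 or 2 and 421 and 751 without E18.5 replicate 1 or 2. Pck1 rose by 5.04 ± 0.52, from 5.2 to 171 ± 49.5 CPM, G6pc by 4.36 ± 0.50, Ugt1a1 by 4.47 ± 0.30 and Tat by 3.77 ± 0.32. All 20 cell cycle genes fell, with a median of -1.70, and this call held with adjusted p = 0.025 with an estimated correlation. Of 12 bile acid genes 7 rose, or 11 adjusted over the list alone, with adjusted p = 0.18 with an estimated correlation. Dlk1 changed by -1.81 ± 0.20, from 1512 to 431 CPM.

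The timing of the course was also read from genes chosen in other libraries, the picked cells described next. Genes that rose there rose early in bulk: their median over genes of log2(CPM + 1), minus its E10.5 mean, was 0.302 at E11.5, 0.591 at E13.5, 0.725 at E15.5 and 0.830 at E18.5. Genes that fell there had lost 0.325 at E11.5, with medians of -0.845 at E13.5, -1.40 at E15.5, -2.17 at E17.5 and -2.51 at E18.5. The E13.5 values come from the libraries with a trend with GC content and were not corrected for it. These values have no test.

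**Figure D2:**
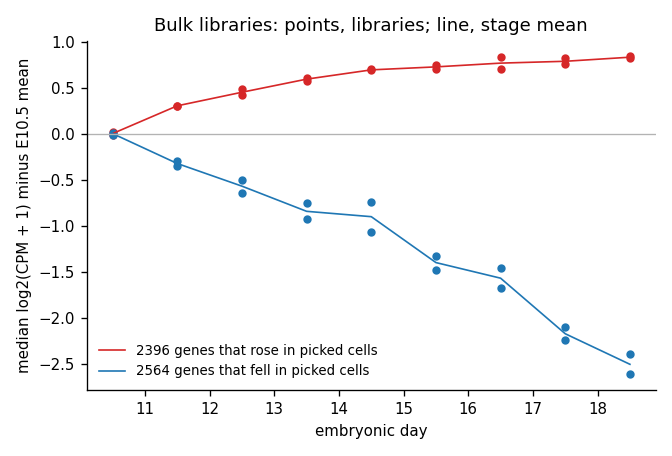
Median over genes of log2(CPM + 1) minus the E10.5 mean, by embryonic day, in the bulk libraries, for 2396 genes that rose and 2564 that fell in picked DLK+ cells from E10.5 to E17.5. Points are libraries and lines join stage means. The first set lies at 0.725 at E15.5 and 0.830 at E18.5, and the second at -1.40 and -2.51.

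Picked DLK+ cells of E17.5 were compared with those of E10.5 (4 sets with 35 cells against 3 sets with 54 cells) to follow the same lineage cell by cell. Alb rose by 6.90 ± 0.46, from 1352 ± 741 to 161111 ± 11239 CPM (adjusted p = 5.4e-13, edgeR's quasi-likelihood test, Benjamini-Hochberg). Ahsg rose by 11.98 ± 0.92, Apoh by 11.45 ± 0.61, Adh1 by 15.23 ± 1.82 and Fbp1 by 14.79 ± 2.19, the latter from 0.107 to 3033 ± 690 CPM. G6pc was at least 674-fold higher and the organic anion transporter Slco1b2 at least 777-fold. Mdk changed by -9.15 ± 0.80, and Lin28a, an RNA-binding protein of early embryonic cells, fell from 63.1 ± 8.56 to 0 CPM. Top2a went from 293 to 10.3 CPM. Dlk1 changed by -1.15 ± 0.33, from 1166 to 524 CPM, and Afp rose by 2.22 ± 0.22. The junction gene Cdh1 rose by 2.52 ± 0.21, while Epcam missed the threshold (-2.12 ± 0.82, adjusted p = 0.05).

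The function lists moved as in bulk and their calls held with an estimated correlation. All 12 plasma carrier genes rose, with a median of 4.64 (adjusted p = 0.0081 with an estimated correlation), and all 19 complement genes, with a median of 5.46 (adjusted p = 0.0031 with an estimated correlation). Of the urea cycle list 13 of 14 rose, or 14 adjusted over the list alone, with a median of 4.81. Of the bile acid list 11 of 12 rose, with a median of 7.63, and of the drug list 11 of 13, or 13 adjusted over the list alone. All 12 fatty acid oxidation genes rose, with a median of 3.36, and all 12 cholesterol synthesis genes, with a median of 1.69 (adjusted p = 0.0066 with an estimated correlation). Of 20 cell cycle genes 17 fell, or 18 adjusted over the list alone, with a median of -2.87 (adjusted p = 0.042 with an estimated correlation). In single cells the plasma carrier score had a median of 7.80 at E10.5 and 12.0 at E17.5, and the cell cycle score 6.75 and 1.65. In all, 2396 genes rose and 2564 fell of 16838 tested. Other splits of the same sets called at most 1 gene, against 5116 for the real one in the same reduced fit.

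Bulk libraries of the same days gave 4774 genes up and 4725 down. Of 14179 genes tested in both, 2217 rose in both and 1982 fell in both, against 760 and 780 for independent lists, and 22 and 7 went opposite ways. Across genes, which are not independent replicates, the log2 changes had Pearson's r of 0.781 and Spearman's rho of 0.779.

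Cells annotated as cholangiocytes, all from the EpCAM+ gate, were next compared with DLK+ gate cells of the same day, averaged over E14.5, E15.5 and E17.5 (9 against 10 sums). The annotation may rest on these same genes, so the differences describe the annotated classes and are not independent evidence. The matrix protein gene Spon1 (ENSMUSG00000038156, chromosome 7, 113765998 to 114043370) was higher in cholangiocytes by 12.77 ± 0.65 (383 ± 86.1 against 0.0722 CPM, adjusted p = 5.3e-15, edgeR's quasi-likelihood test, Benjamini-Hochberg). Spp1 was higher by 10.54 ± 0.69 (3364 ± 3231 against 1.56 CPM), Sox9 by 8.10 ± 0.77 (495 ± 115 against 4.21 CPM) and Epcam by 6.60 ± 0.63 (404 ± 119 against 7.44 CPM). The keratin Krt19 had 45.3 ± 36.6 CPM against 0.0132. All 13 early biliary genes were higher, with a median of 6.98, and of 16 mature biliary genes 10 were higher and 1 lower, with a median of 3.53. Of 17 junction and basement membrane genes 15 were higher, such as Cldn6 (9.92 ± 0.67) and Cldn3 (5.49 ± 0.54).

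Signalling genes differed too. Of 10 YAP targets 9 were higher in cholangiocytes, or 10 adjusted over the list alone, with Ctgf at 97.6 against 0.0727 CPM. Of 10 Notch pathway genes 5 were higher and 1 lower, with a median of 2.69 and adjusted p = 0.053 with an estimated correlation. This call was also lost without any one of 7 replicates. The ligand Jag1 was higher by 8.39 ± 0.99 and the Notch target Nrarp by 6.85, while the receptor Notch1 was lower (-2.80 ± 0.65). Etv4, a transcription factor induced by ERK signalling, was higher by 6.83 ± 0.92.

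Hepatocyte functions were lower in cholangiocytes. All 12 cholesterol synthesis genes were lower, with a median of -2.18, including Fdps (-2.84 ± 0.11). Of the bile acid list 10 of 12 were lower, with a median of -4.33, and of the urea cycle list 12 of 14, with a median of -2.60. Of 12 plasma carrier genes 11 were lower and 1 higher, with a median of -1.54 and adjusted p = 0.053 with an estimated correlation, and of 19 complement genes 13 were lower and 1 higher, with adjusted p = 0.12 with an estimated correlation. The difference in Alb was only -1.33 ± 0.21 (29937 ± 10589 against 95792 ± 57977 CPM). The receptor Asgr1 (-9.54 ± 0.61) and glycogen synthase Gys2 (-6.76 ± 0.57) were far lower. In all, 3199 genes were higher and 2696 lower, and 40 of 14000 splits of the sets were run, of which those other than the real one called at most 1 gene, against 5275. Groups that may be defined by expression are expected to exceed random splits, so this says nothing about chance.

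At E14.5 the EpCAM+ gate held both annotated types in each of 3 sets (17 cholangiocytes and 26 hepatoblasts). The annotation may rest on the same genes here too, so the differences describe the annotated classes and are not independent evidence. Comparing both types in this gate removes gate, day and set as differences. Within it Spp1 was higher in cholangiocytes by 8.63 ± 1.13 (699 ± 506 against 1.61 CPM), Krt7 by 5.90 ± 0.79, Epcam by 4.47 ± 0.97 (325 ± 116 against 14.3 CPM) and Sox9 by 3.56 ± 1.05 (392 ± 21 against 33.4 ± 35.2 CPM, adjusted p = 0.025, edgeR's quasi-likelihood test, Benjamini-Hochberg). The cadherin Cdh3 was at least 141-fold higher and the gap junction gene Gja1 at least 92.6-fold. Of 13 early biliary genes 9 were higher, with a median of 4.47, and of 10 YAP targets 5, or 8 adjusted over the list alone. Of 10 Notch pathway genes 3 were higher, with a median of 1.49 (adjusted p = 0.042 with an estimated correlation), a call lost without hepatoblast replicate 1. All 12 cholesterol synthesis genes were lower, with a median of -1.86 (adjusted p = 0.00021 with an estimated correlation), and Gys2 went from 337 to 7.34 CPM. Alb (-0.64, adjusted p = 0.28) and Dlk1 (-0.56, adjusted p = 0.33) did not pass the test. In all, 758 genes were higher and 1104 lower, while a reduced fit of the compared sums alone called 827 genes. Sox9 lost its call without the second deposit round and without hepatoblast replicate 1 or 3. Only 10 splits of these sets exist, too few to set the count against chance.

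The share of EpCAM+ gate cells annotated as cholangiocytes grew with age. It was 5.88% at E11.5 (2 of 34 cells, exact binomial 95% interval 0.720 to 19.7), 15% at E12.5 (3 of 20, 3.21 to 37.9) and 38.5% at E13.5 (10 of 26, 20.2 to 59.4). It was 39.5% at E14.5 (17 of 43, 24.98 to 55.6), 94.7% at E15.5 (36 of 38, 82.3 to 99.4) and 97.1% at E17.5 (34 of 35, 85.1 to 99.9). Sets differed widely at E12.5 (0 and 50%) and E13.5 (1 of 8 cells and 9 of 18), which the binomial intervals do not cover. They ranged from 36.8 to 45.5% at E14.5, from 90.9 to 100% at E15.5 and from 93.75 to 100% at E17.5, and were 0 and 7.69% at E11.5. Over 15 sets the share followed embryonic day with Pearson's r of 0.883 (permutation p = 3.0e-05, two-sided) and Spearman's rho of 0.861 (permutation p = 1.0e-04). Without the 2 sets farthest from the median day, r was 0.834 (permutation p = 0.00056) and rho 0.801 (permutation p = 0.00174). Without the second deposit round, which held only a set of E14.5, r was 0.890 and rho 0.872. This was the only correlation across samples computed.

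**Figure D3:**
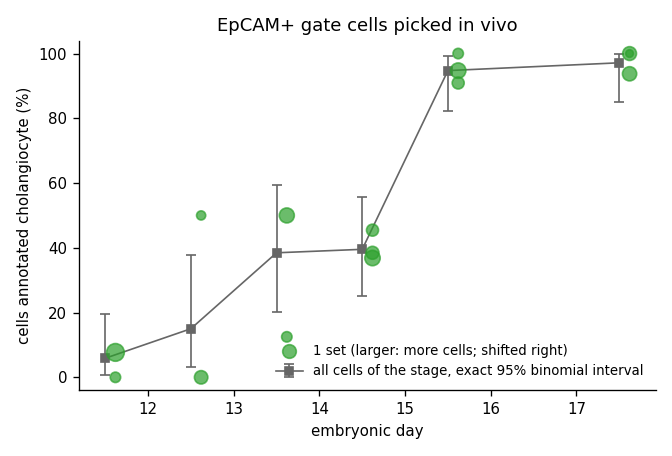
Share of EpCAM+ gate cells annotated as cholangiocytes, in percent, by embryonic day. Bars are exact 95% binomial intervals of a stage and green dots are sets. The share lies at 39.5% at E14.5 and at 94.7% at E15.5.

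To follow maturation after the annotation first appears, cholangiocytes of E17.5 were compared with those of E14.5 (34 and 17 cells, 3 sums each). Spp1 rose by 3.36 ± 0.85, from 699 ± 506 to 7157 ± 1829 CPM (adjusted p = 0.023, edgeR's quasi-likelihood test, Benjamini-Hochberg). Complement C3 rose by 1.29 ± 0.28, the apical enzyme Ggt1 by 1.93 ± 0.48 and Cdh1 by 0.87 ± 0.20. The chaperone Cryab was at least 127-fold higher. Dlk1 changed by -3.42 ± 0.39, from 702 ± 354 to 65.3 ± 25.8 CPM, Afp by -1.57 ± 0.22, the apolipoprotein Apoa1 by -2.65 ± 0.39 and the acetyl-CoA synthetase Acss1 by -3.94 ± 0.30. Sox9 (0.33, adjusted p = 0.96), Epcam (0.70, adjusted p = 0.77), Krt19 (1.13, adjusted p = 0.74) and Alb (0.23, adjusted p = 0.85) did not pass the test. The call of Spp1 was lost with DESeq2 and without E14.5 replicate 2 or 3 or E17.5 replicate 4, that of Ggt1 without E14.5 replicate 2 or 3 or E17.5 replicate 3, and that of Cryab without any one E14.5 replicate. C3 lost its call without E17.5 replicate 4, and Cdh1 without that or E14.5 replicate 2.

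Of 14 fetal liver genes 5 fell with this maturation, or 7 adjusted over the list alone, with a median of -0.91 (adjusted p = 1.7e-05 with an estimated correlation). Of 12 cholesterol synthesis genes 8 fell, or 9 adjusted over the list alone, with a median of -1.03 (adjusted p = 0.015 with an estimated correlation). Of 17 junction and basement membrane genes 2 rose, or 4 adjusted over the list alone, with a median of 0.75 (adjusted p = 0.015 with an estimated correlation). The mature biliary list was called as a rise with 1 of 16 genes past the test and a median of 1.24, and had adjusted p = 0.21 with an estimated correlation. Without E14.5 replicate 2 or E17.5 replicate 4 this call was lost. In single cells the early biliary score had a median of 3.77 at E14.5, 4.30 at E15.5 and 4.90 at E17.5, against 0.69 in DLK+ gate cells of E17.5, and the mature biliary score 1.95, 2.29 and 2.61 against 1.21. Their plasma carrier score still had a median of 9.597 at E17.5, against 12.0 in DLK+ gate cells. In all, 195 genes rose and 358 fell, with 351 called without E17.5 replicate 3. A reduced fit of the compared sums alone called only 54 genes. The X-inactivation RNA Xist differed between the stages compared, with 106 ± 69.5 CPM at E14.5 and 0.0867 at E17.5. What set the sets of these stages apart in this RNA cannot be separated from maturation in this contrast.

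Cells annotated as hepatoblasts were compared between the EpCAM+ and DLK+ gates from E11.5 to E14.5. Only 4 genes, all higher in the EpCAM+ gate, passed edgeR's quasi-likelihood test (826 at an unadjusted p below 0.05). These were Cdh1 (0.87 ± 0.11, Benjamini-Hochberg adjusted p = 0.00019), the phospholipase Pla2g7 (1.43 ± 0.21), Epcam (3.27 ± 0.55, 32.2 ± 27.8 against 4.84 CPM) and Cystm1 (1.26 ± 0.23). Epcam codes for the protein on which the EpCAM+ gate was sorted, so its difference is not an independent result. Sox9 had 27.8 against 4.29 CPM (3.32 ± 0.66, adjusted p = 0.064). The junction list was higher in the EpCAM+ gate, with 1 of 17 genes past the test, or 4 adjusted over the list alone, and adjusted p = 0.00056 with an estimated correlation. Epcam lost its call without E12.5 DLK+ replicate 2, and Cystm1 in 9 of the fits with a replicate left out. Alb, Afp, Dlk1 and Spp1 had an adjusted p = 1.0. The count was 82 without E12.5 EpCAM+ replicate 1, 15 with no filter and 66 with DESeq2, and 6 of 40 splits of the sets, drawn from 12000 and with the real one included, called at least as many genes as the real one in a reduced fit, so chance is not excluded.

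In explants, TPPB was the only treatment for which the main edgeR fit called genes against control in EpCAM+ cells. It had 2 sets with 22 cells, against 4 control sets with 24 cells. TPPB was given only in the first deposit round, so its fitted changes rest on control sets 1 and 2. Control levels are means over all 4 sets. Liver proteins fell far. Alb changed by -8.73 ± 1.29, from 29272 ± 18437 to 78.1 ± 81 CPM (adjusted p = 0.0069, edgeR's quasi-likelihood test, Benjamini-Hochberg), Afp by -6.64 ± 1.19, from 79719 ± 35319 to 846 ± 929 CPM, and Ahsg by -13.20 ± 1.31, from 16811 ± 10445 to 1.78 CPM. Igfbp1, a secreted binding protein of insulin-like growth factors, went from 13479 ± 3584 to 0.784 CPM, and the protease inhibitor A2m was at least 5317-fold lower. Of 12 plasma carrier genes 11 fell, or 12 adjusted over the list alone, with a median of -10.08 (-8.39 with unseen genes at their bound), and of 18 complement genes 11 fell, or 18 adjusted over the list alone, with a median of -9.86 (-8.55). Both calls held, with adjusted p = 0.03 with an estimated correlation. Of 12 fatty acid oxidation genes 5 fell, or 9 adjusted over the list alone, with a median of -2.27 and adjusted p = 0.086 with an estimated correlation. No cholesterol synthesis gene passed over all genes tested, and 10 of 12 did adjusted over the list alone, all lower, with adjusted p = 0.17 with an estimated correlation. Of 19 liver transcription factors 2 fell, or 5 were called adjusted over the list alone, and camera did not call the list (adjusted p = 0.080 with the preset correlation). These 2 were Cebpa (0.105 against 19.3 CPM) and Foxa3 (-2.44 ± 0.45). The calls of Afp, Cebpa and Foxa3 were lost without control replicate 1, and those of Cebpa and Foxa3 also without either TPPB replicate, while Alb kept its call in every setting.

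Only 11 rises with TPPB were called, but 1922 genes had a fitted rise of over 2 log2 units, against 1315 with a fall of over 2, and 782 rises had an unadjusted p below 0.05, against 1122 falls. Sox11, a progenitor transcription factor, rose by 3.40 ± 0.53, from 21.6 ± 9.13 to 285 ± 19.7 CPM, the protease Adamts1 by 5.27 ± 0.68, the cyclin Ccnd2 by 3.61 ± 0.74, the junction protein Jup by 1.98 ± 0.37 and Spon1 by 10.24 ± 2.09, from 0.21 to 103 CPM. These calls were less firm: Ccnd2, Jup and Spon1 lost theirs without control replicate 1 or 2 or either TPPB replicate, Sox11 without control replicate 2 or TPPB replicate 1, and Adamts1 without control replicate 1. The biliary markers were higher in the group means without passing the test: Epcam had 1020 ± 84.3 against 198 ± 130 CPM (2.05 ± 0.79, adjusted p = 0.29), Krt19 532 against 164 CPM (adjusted p = 0.56), Sox9 336 against 107 CPM (adjusted p = 0.28) and Spp1 8644 ± 1151 against 1625 ± 3248 CPM (adjusted p = 0.92). The early biliary list rose, with 1 of 14 genes past the test, or 4 adjusted over the list alone, a median of 1.90 and adjusted p = 0.074 with an estimated correlation. The mature biliary list rose with 0 of 17 genes, or 3 adjusted over the list alone, a median of 2.75 and adjusted p = 0.074 with an estimated correlation. The cell cycle list rose with 0 of 20 genes past the test, a median of 1.98 and adjusted p = 0.24 with an estimated correlation. Camera also called the junction, Notch and YAP lists as rises and the urea cycle, gluconeogenesis, bile acid, drug and fetal liver lists as falls, none of which held with an estimated correlation (adjusted p = 0.086 to 0.24). The fetal liver call was also lost without control replicate 1, 3 or 4 or TPPB replicate 1. The mean of the cell cycle list in the control sets, from set 1 to set 4, was 3.59, 4.85, 6.08 and 5.10 log2 CPM, against 6.07 and 6.85 with TPPB. Per cell, the early biliary score had a median of 6.91 with TPPB and 2.92 in controls, and the plasma carrier score 2.41 and 9.96. In all 11 genes rose and 260 fell of 13749 tested, 146 in all without control replicate 1. DESeq2 called 990. One of the TPPB sets, set 2, carried more red cell RNA, with a list mean of 5.17 log2 CPM against 0.82 in set 1.

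**Figure D4:**
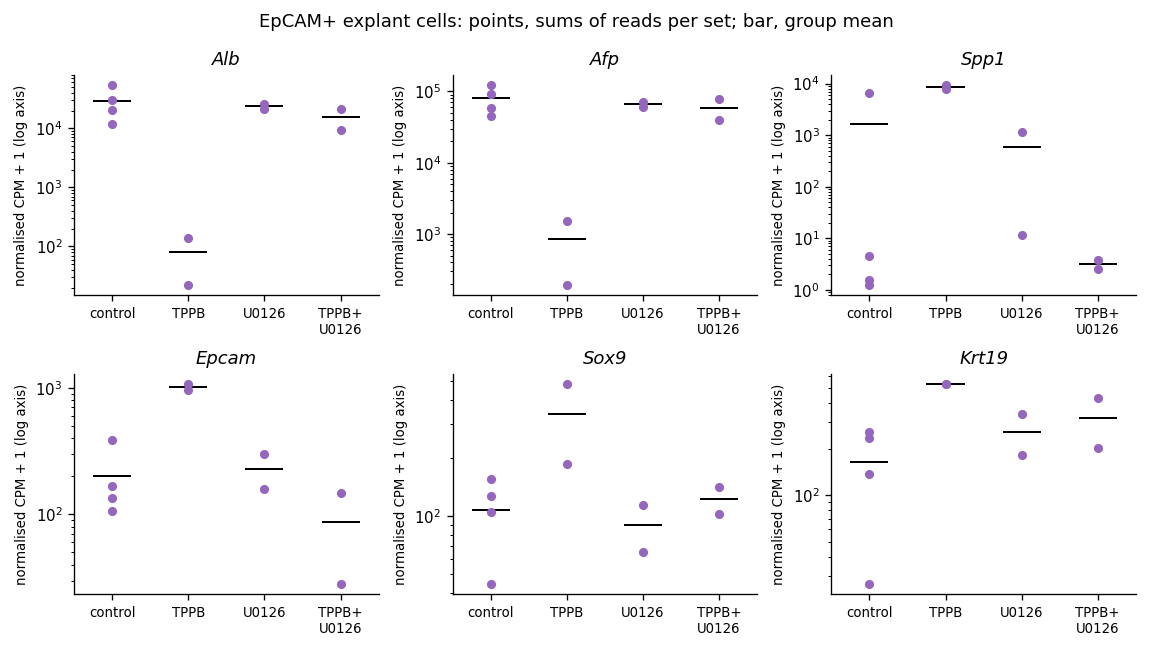
Normalised CPM plus 1 on a log axis of 6 marker genes in EpCAM+ cells of explants, by treatment. Points are set sums, 4 of control and 2 of each other treatment. Alb averages 29272 CPM in controls, 78.1 CPM with TPPB and 15496 CPM with TPPB and U0126.

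With U0126 alone, edgeR called 0 genes (288 at an unadjusted p below 0.05, 31 called by DESeq2, 86 with no filter). U0126, alone or with TPPB, was given only in sets 3 and 4. Fitted changes against control therefore rest on control sets 3 and 4, with 10 and 2 cells, and can oppose the group means. With U0126 alone, Spp1 had 593 against 1625 CPM but a fitted change of 10.99. Alb had 23496 CPM against 29272 in controls (-0.11, adjusted p = 1.0), Epcam 229 against 198 CPM and Sox9 89.1 against 107 CPM. Cyp1a1, a target of the aryl hydrocarbon receptor, had 1174 ± 211 against 0.403 CPM (9.93 ± 0.98) with a Benjamini-Hochberg adjusted p = 0.15, and Hp 1882 against 107 CPM (adjusted p = 0.74). Camera called the early biliary list as a rise (median 1.35) and the cell cycle list as a fall (median -1.26), and the YAP and junction lists as rises and the fatty acid oxidation and cholesterol synthesis lists as falls. All 6 calls were lost with an estimated correlation (adjusted p = 0.40 to 0.84). The early biliary, YAP and junction calls were also lost without control replicate 3, YAP without U0126 replicate 4 and junctions without U0126 replicate 3, and both metabolic calls without control replicate 4 or U0126 replicate 4. The list of ERK feedback and immediate targets, which would report on MEK, was not called (mean 4.13 against 3.92 log2 CPM, adjusted p = 0.77), and Dusp6 (222 ± 157 against 390 ± 138 CPM) and Ier3 (260 ± 167 against 114 ± 104.2 CPM) had an adjusted p = 1.0. TPPB with U0126 against control also called 0 genes with edgeR (644 at an unadjusted p below 0.05, 110 called by DESeq2, 127 with no filter). Cyp1a1 had 1351 ± 863 CPM (adjusted p = 0.13) and Hp 5410 ± 272 CPM (adjusted p = 0.24). Camera called the cell cycle, cholesterol synthesis and fatty acid oxidation lists as falls and the YAP list as a rise, all lost with an estimated correlation (adjusted p = 0.28 to 0.57). Both metabolic calls were also lost without control replicate 4 or replicate 3 of both drugs, and that of YAP without control replicate 3. Without control replicate 3, 396 and 435 genes were called in these comparisons. In simulated data for both, 0% of 4-fold changes were recovered, so changes of that size can be missed.

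Cells given both drugs had liver proteins at high levels. Against TPPB alone, they had Alb at 15496 ± 8487 instead of 78.1 CPM (8.03 ± 1.47, adjusted p = 0.037, edgeR's quasi-likelihood test, Benjamini-Hochberg, 2 against 2 sets), Ahsg at 9555 instead of 1.78 CPM (12.39 ± 1.42) and fibrinogen Fga at 5999 instead of 2.13 CPM (11.63 ± 1.24). Glul was higher by 3.15 ± 0.50. Of 12 plasma carrier genes 10 were higher, or 12 adjusted over the list alone, with a median of 9.19 (7.95 with unseen genes at their bound), and of 18 complement genes 11, or 17 adjusted over the list alone, with a median of 10.08 (7.87). Both calls held, with adjusted p = 0.049 with an estimated correlation. The urea cycle and fatty acid oxidation lists were also called as higher, and the cell cycle (median -3.80), junction and early biliary lists as lower, the last 3 with 0 genes past the test, and none of the 5 held with an estimated correlation (adjusted p = 0.25 to 0.34). The early biliary call was also lost without TPPB replicate 2 and the urea cycle call without TPPB replicate 1. Epcam had 86.5 against 1020 CPM (-2.83, adjusted p = 0.36) and Spp1 2.17 against 8644 ± 1151 CPM (adjusted p = 1.0). In all 133 genes were higher and 0 lower, 50 with sums of at least 5 cells, 73 with annotated cholangiocytes only and 642 with DESeq2. With sums of at least 5 cells, Alb, Fga and Glul lost their calls, as Alb also did without replicate 4 of both drugs and Glul without replicate 3 or either TPPB replicate. TPPB was given in sets 1 and 2 and both drugs in sets 3 and 4, so this contrast runs across deposit rounds linked by the controls. The fitted change can therefore oppose the group means, as for Spp1 (fitted 1.46). Against U0126 alone, both drugs called 0 genes with edgeR (249 at an unadjusted p below 0.05, 26 called by DESeq2, 52 with no filter).

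The genes of in vivo maturation, those changed in cholangiocytes from E14.5 to E17.5, were then read in the explants. The genes that fell in vivo also fell with TPPB, with a median of -1.09 over 351 genes and adjusted p = 0.0174 with an estimated correlation. They were higher with both drugs than with TPPB (median 1.08, adjusted p = 0.072 with an estimated correlation). Both contrasts rest on the same TPPB sums, so the opposite sign of the second is not independent evidence. The 185 genes that rose in vivo had a median of -0.37 with TPPB, a call that had adjusted p = 0.0757 with an estimated correlation, and 0.18 with sets taken from the linear change per day (adjusted p = 0.823). With U0126 alone the genes that fell in vivo were not called (adjusted p = 0.114 with the preset correlation).

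Shares of EpCAM+ explant cells annotated as cholangiocytes were 91.7% in controls (22 of 24, exact binomial 95% interval 73.0 to 99.0), 100% with TPPB (22 of 22, 84.6 to 100), 86.7% with U0126 (13 of 15, 59.5 to 98.3) and 100% with both (9 of 9, 66.4 to 100), so their intervals overlap. The DLK+ gate held 0 annotated cholangiocytes in 6 control cells and 0 in 6 TPPB cells (0 to 45.9). With 1 set of more than 1 cell per group there, these cells have values only. Their summed levels were 40179 CPM of Alb in controls and 48981 with TPPB, 85459 and 90318 of Afp, 12510 and 19515 of Apoa1, and 4.86 and 6.72 of Epcam. The red cell gene Hbb-bs had 8.72 and 946 CPM.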

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

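A rule was applied to 63 marker levels and list means in the 2 groups with 4 replicates, DLK+ gate cells of E17.5 and EpCAM+ cells of control explants. The gap of the highest or lowest replicate to its nearest neighbour, over the range of the group, was set against Dixon's 95% critical value. It flagged 4 of the 63, close to the 1 in 20 or so that chance flags. Among those flagged, the gap over the range was 0.999 for Spp1 and 0.831 to 0.837 for the list means. Values from the same replicates are not independent. In EpCAM+ cells of control explants, set 1 had 6496.52 CPM of Spp1, a bile duct marker, while the other 3 sets had 0.220 to 3.55. In DLK+ gate cells of E17.5, set 1 had a mean of 7.67919 log2 CPM over the amino acid and urea cycle genes, against 8.07 to 8.15 in the other 3 sets. In the same cells, set 3 had 8.16657 over the gluconeogenesis and glycogen genes, against 8.46 to 8.51, and set 1 had 8.95339 over the cholesterol synthesis genes, against 8.63 to 8.68.

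The effect of TPPB was also flagged, because it differed between explants with and without U0126 by a test of the difference itself. The test of this difference was chosen after the data were seen. In edgeR's quasi-likelihood test of it, 152 genes passed (146 higher and 6 lower with U0126 present). These numbers were 80 and 0 without control replicate 1, and 159 and 10 without control replicate 4. Apom, an apolipoprotein, differed by 13.53 ± 0.75 (Benjamini-Hochberg adjusted p = 0.00012), the liver transcription factor Creb3l3 by 8.17 ± 0.68 and the bile canaliculus pump Abcc2 by 9.53 ± 0.82, genes chosen after their values were seen. TPPB was given without U0126 only in the first deposit round and with U0126 only in the second, with 2 sets per treated group. A response to TPPB that differed between rounds would give the same result, so these genes cannot be assigned to U0126. The count was 149 with DESeq2 size factors, 70 without U0126 replicate 3 and 169 without control replicate 4, alternatives chosen after seeing the data.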

How the results depend on the processing

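Of the values that answer comparisons, 120 stayed on their side of the threshold under other settings, 28 passed it or at least grew 1.5 times, 14 weakened and 4 moved. Of named gene values, 9982 were unchanged in call, 220 became stronger, 406 weaker and 6 reversed, and with 1 replicate left out 9324, 53, 994 and 1. Where no cause is named, the cause was not tested. With no filter on low counts, the called genes numbered 835 (bulk E12.5 against E11.5), 755 (E15.5 against E14.5), 323 (E16.5 against E15.5), 15 (gates), 856 (TPPB against control), 86 (U0126 against control), 127 (both drugs against control), 52 (both against U0126) and 629 (both against TPPB). With DESeq2 they numbered 439, 399, 7, 66, 990, 31, 110, 26 and 642 in the same order, and 1034 for cholangiocytes E17.5 against E14.5. With GC trends removed, 215 (E13.5 against E12.5) and 543 (E14.5 against E13.5) were called. Equal weight of cells gave 8500 (picked cells E17.5 against E10.5), 1246 (cholangiocytes), 826, 1 and 2 (TPPB, U0126 and both against control). A linear change per day gave 362 in cholangiocytes. No round term gave 519, 1 and 1 against control and 356 for both against TPPB, where sums of at least 5 cells gave 50 and annotated cholangiocytes alone 73. Of 191 list calls, 37 held with an estimated correlation.

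With an estimated correlation the in vivo maturation genes that fell kept their call with TPPB against control (adjusted p = 0.0174), and their other calls in explants were lost at unchanged medians. For genes that rose, these were -0.365047 (TPPB against control, adjusted p = 0.0757) and 0.471623 (both against TPPB). For genes that fell, they were -0.244901 (both against control), -0.229277 (both against U0126) and 1.08018 (both against TPPB). With sets from the linear change per day, the medians were 0.182685 (rose, TPPB against control), -0.00700678 (rose, both against TPPB) and -0.229277 (fell, both against U0126). The bulk timing of genes that rose ended at 0.972595 with a pseudocount of 0.1 and 0.711662 with a mean of at least 10 CPM, and that of genes that fell at -2.758 with a pseudocount of 0.1. Of 28 values before E18.5 under these settings, 13 moved and 15 did not. The E13.5 values were not recomputed with GC trends removed. The early biliary score difference was 5.74946 instead of 4.21281. Reversed were Skil (-0.177646, picked cells, equal weight) and, with GC trends removed, Bub1 (0.107564, E13.5 against E12.5), Bub1 (-0.216426), Otc (-0.141363), Foxa2 (0.0512547) and Lin28b (-0.268931, all E14.5 against E13.5).

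Leaving out each replicate in turn gave counts of 651 to 1031 (E11.5 against E10.5), 4 to 423 (E12.5 against E11.5), 527 to 2450 (E13.5 against E12.5), 2034 to 3161 (E14.5 against E13.5), 0 to 612 (E15.5 against E14.5), 0 to 14 (E16.5 against E15.5), 728 to 1676 (E17.5 against E16.5) and 421 to 751 (E18.5 against E17.5). A stage left with 1 library is assumed to vary like the others. The ranges were 351 to 551 for cholangiocytes, 2 to 82 between gates, 146 to 345 (TPPB against control), 0 to 396 (U0126), 0 to 435 (both) and 70 to 169 for the difference between TPPB effects. Medians of maturation genes that fell ranged from -0.141 to 0.215831 (U0126 against control), -0.603507 to -0.00412146 (both against control) and -0.604123 to -0.0471815 (both against U0126). Msln in bulk E18.5 vs E10.5 ranged from -4.73277 to 4.3045.

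Deviations of same-numbered bulk libraries correlated with a median of 0.0012 over 36 pairs (-0.67 to 0.42), and those of explant sums with -0.024 over 8, so the numbers do not pair these. Sums from embryos of 1 day that share a set number correlated weakly (median 0.083 over 20 pairs, 0.0041 to 0.43, 9 over 0.1, against -0.071 for other numbers), and the fit has no set term. With stage and set as a block, 4214 genes were called between cholangiocytes and hepatoblasts or hepatocytes, 1313 within the EpCAM+ gate and 4 between gates. With a replicate block, E18.5 against E10.5 gave 9877 genes and TPPB against control 234, and no count with a block moved by over 1.5 times. The alternative minimum of 4000 genes per cell gave no value, since every cell had at least 6682. In explants, whose EpCAM+ sums held 1935026 to 13737444 reads, no simulated 4-fold change was recovered, and whether depth, the number of sets or their spread limits this was not tested.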

Other observations

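The predictions of every test in this part were written before its result was seen. The correction for GC content was chosen after the libraries had been examined. That some of the tests cannot tell for reasons of their design was judged after their results were seen.

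Cells that the authors annotated as cholangiocytes carried hepatocyte transcripts from the first. The 2 such cells of E11.5 had a plasma carrier score, the mean of log2(TPM + 1) over 12 genes, with a median of 10.9, against 9.75 in 32 EpCAM+ gate hepatoblasts of the same day. The 3 such cells of E12.5 had a median of 11.46, against 10.08 in 17 EpCAM+ gate hepatoblasts of that day. All 3 came from set 2, while 14 of these hepatoblasts came from set 1, so set and annotated type are mixed there. In explant cells with TPPB the same score had quartiles of 1.93 and 2.74. Mature biliary scores were 3.91 with TPPB, 1.53 in controls, 1.61 with U0126 and 1.68 with both, and cell cycle scores 4.01, 1.93, 2.12 and 1.87. Cells of a group are not replicates, and none of these scores has a test.

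In TPPB explants the fetal liver list had a median log2 change of -0.01 but a mean of -0.42, and the drug metabolism list a median of -0.27 and a mean of -2.09, since genes of these lists moved by very different amounts. With both drugs, Spry1, a feedback inhibitor of ERK signalling (0 against 21.5 ± 20.2 CPM), and Prkca, a protein kinase C (0 against 9.68 CPM), went unseen in sums where U0126 alone left reads, but neither passed edgeR's quasi-likelihood test.

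Many bulk genes were called between E13.5 and E14.5. If the GC content of the E13.5 libraries made these calls, under 50% should remain once each library's trend with GC content is removed, and 9.78049% remained (401 of 4100, among 543 then called), which fits this cause. The removal would also take away a real stage difference that follows GC content. Across genes, the change followed GC content with rho of -0.67 in bulk and -0.067 in picked DLK+ cells of the same days. If they were changes within hepatoblasts, at least 70% should have the same sign in picked DLK+ cells, and 63.1817% did (interval 61.7 to 64.7), between both predictions, so this test cannot tell. Deviations of the E13.5 libraries from the mean log2(CPM + 1) of all bulk libraries followed GC content with Spearman's rho of 0.68 and 0.76 across genes. A separate set of bulk libraries from E13.5 would settle the size of the remaining change.

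Against the day before, the mean log2 change of the stellate and mesenchymal list in bulk was -1.25 at E11.5, 0.95 at E12.5 and 0.24 at E13.5. It was -0.14 at E14.5, -0.44 at E15.5, -1.11 at E16.5 and -1.96 at E17.5. From E10.5 to E17.5, 11 of its 13 genes were called as falls in bulk. If this came from RNA of other cells in the sorted samples, these genes should lie at least 3 log2 units higher in bulk than in picked cells of E10.5, and their median lay 4.86087 higher over 11 genes, which fits. Col1a1 had 430 CPM in bulk and 0 in picked cells. A fall within hepatoblasts predicts that at least 6 of the members also fell in picked cells, and 2 did, Col1a2 and Reln, so this test alone cannot tell. All 11 genes but Reln lay at 0 to 3.62 CPM in picked cells of E10.5, against 4.68 to 430 CPM in bulk. For these genes the levels argue against a fall within hepatoblasts as the source of the bulk fall. Reln, with 247 CPM in picked cells and 1712 CPM in bulk, fell in both.

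With TPPB 260 falls and 11 rises were called. The excess is in the calls: fitted rises of over 2 log2 units numbered 1922 and falls of over 2 numbered 1315. If a few abundant genes had skewed the scaling, the share of falls should drop below 65% with DESeq2 size factors. It stayed at 94.9416% (95.941% with TMM). Both ways of scaling limit the weight of a few abundant genes and could share a skew, so the result cannot tell. If a wider spread between control sets hid the rises, the median SD of genes with a fitted rise should be at least 1.5 times that of genes with a fall, and the ratio was 0.724031. This test cannot tell, since the rising genes had a median of 0.704 CPM in controls, where the floor holds the spread down. Fitted rises had a larger median SE than falls (2.53 against 1.88). A lower precision of rises therefore stays open as a reason for the excess of called falls, as does a skew of the scaling. A loss of the hepatocyte program under protein kinase C activation, which rests on 2 sets from 1 deposit round, also stays open.

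Chance was tested by splitting the same sets in other ways. For picked DLK+ cells of E17.5 against E10.5, all 35 splits were run, and 1, the real one, called as many genes (5116, at most 1 in the others). A share of 1 in 35 is the lowest these splits can give, and every other split mixes both stages. This speaks against chance without excluding it, and does not address other differences between the sets of both stages. For annotated cholangiocytes against hepatoblasts and hepatocytes, 40 splits were drawn from 14000, and 1, the real one, called as many (5275, at most 1 in the others). The annotation may rest on the same genes, which would set the real split apart by construction, so this test cannot tell. Within the EpCAM+ gate at E14.5 (827, at most 0 in the others) and for cholangiocytes of E17.5 against E14.5 (54, at most 0), 1 of 10 splits did in each, too few splits to tell. Between gates, 40 splits were drawn from 12000 and 6, the real one included, called at least as many genes as the real one (1, at most 3 in the others), so chance is not excluded.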
